A study of Homo sapiens with 8 samples.

How the data were processed

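RIP-seq was done in IHCF, an immortalized human cardiac fibroblast line, with an antibody against eIF4G2, in cells with a lentiviral eIF4G2 vector or a scramble control vector. Per the labels, total and eIF4G2-bound RNA were sequenced in 2 biological replicates per condition, 8 libraries in all. RNA was treated with DNase, enriched for poly(A) and made into libraries with the NEBNext Ultra II kit for paired-end sequencing, per the series' design text. The submitters' processing notes name bcl2fastq 2.19.0, Trimmomatic 0.36, HISAT2 2.1.0 and the GRCh38 (hg38) build. The region caller, its threshold, the use of the total RNA libraries as background and the treatment of replicates are not given in the sources used here.

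The authors deposited 1 table of bound regions per condition, in which each region is repeated for every Ensembl transcript it overlaps or lies nearest to. The values are 1-based positions, region widths and distances to transcripts in bp, with no normalization, per the file headers. The tables give no strand for regions, and no read count, score, fold or p-value, so the depth behind a region is unknown. A region stands for RNA the caller placed above its own threshold, and a gene without a region is not shown to be unbound. No column of per-sample values exists, so the planned tests per replicate, which needed counts, could not be made. Table names alone tell which condition a table belongs to.

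Region numbers run from 1 to 1986 and from 1 to 1224 with 0 missing, and in every case the width matched the ends. Regions were compared with bedtools 2.31.1, counting an overlap of at least 1 bp. A gene counted as listed if a region lay inside it or overlapped it; genes that were only nearest to a region were left out. Genes were counted by Ensembl identifier: 861 had a region in either list and 733 of these had a name. RefSeq gene records of GRCh38.p14 gave the gene type, chromosome and length for 725 of the named genes; 8 did not match. The chromosome was the same in both sources for all 725.

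The gene lists, the comparisons and the rule for named genes were set before the data were examined. The rule took EIF4G2, the 10 highest-scoring genes in the overexpression list only, in the control list only and in both, and the 4 highest members of each of 20 gene lists. Clones, unnamed loci and small RNAs were left out of the groups of 10. Since the tables hold no score, the widest region of a gene took its place, and for genes in both lists the smaller of the widest regions, a change made after the columns were seen. Shares of regions have 95% Wilson intervals. Gene lists with at least 3 listed members were set against 10000 random sets of the same size, drawn from the 725 genes in 5 classes of summed region width, and the percentage of sets with as many genes is a description of these lists, not a p-value. Overexpression regions of chromosome 4 were placed at random within the span of their genes 1000 times. Covered length per gene, in bp, was compared as a ratio because the deposited tables held no count. It is the summed full width of the regions of a gene, including parts that lie beyond the gene. A region over several genes counted in full for each of them.

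Alternative settings chosen beforehand were merging of regions up to 1000 bp apart, overlap of at least 50% of the shorter or of both regions, nearest genes, protein-coding genes only, other matching of the random sets, the widest region in place of the sum, and weighting by width. Alternatives added after the data were seen were chromosome 4 only, chromosome 18 left out, regions of at least 400 bp, regions over 1 gene only, regions with boundaries on both bin grids, sets matched on chromosome, random sets for members with a region in either list, random placement at the relative positions of other regions, and unscaled lengths. The overlap counts and the random sets were tested on simulated data. Of regions planted on 200 of the 491 overexpression regions of chromosome 4, 200 were found. Of simulated lists of 20 genes among 600, 3.0% with no change and 95% with a strongly raised share came out in the top 5% of random sets. The gene lists compared had fewer listed members (5, 5 and 13), so the 95% does not carry over to them. For a list of 5, even 4 genes in the overexpression list only were matched by 8.70% of sets. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

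The procedure limits what the lists can show. Regions of a few chromosomes make up nearly the whole of each list, so a gene's presence in 1 list and absence from the other mixes a difference in binding with a difference between chromosomes, and values within chromosome 4 are given beside those over all chromosomes. Long transcripts offer more positions for a region: on chromosome 4, coding genes with a control region had a median length of 56.9 kb, those with an overexpression region 64.9 kb and those without a region 26.9 kb.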

Results

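RNA bound by eIF4G2, a translation initiation factor related to eIF4G1 that lacks the binding site for the cap-binding protein, was recovered by immunoprecipitation and sequenced (RIP-seq) from IHCF, an immortalized line of human cardiac fibroblasts. The cells carried a lentiviral vector for full-length eIF4G2 or a scramble control vector. The 8 libraries fall into 4 groups of 2: total RNA and eIF4G2-bound RNA of control cells, and total RNA and eIF4G2-bound RNA of overexpressing cells. The data used here are 2 lists of bound regions, 1 per condition, called the control list and the overexpression list below. Which list belongs to which condition rests on the authors' names for the tables alone; these names also hold the name of MOV10, another RNA-binding protein, which no sample label mentions. The lists give positions and overlapping transcripts on GRCh38, with no read count, score, fold or p-value and no value per replicate. Depth is therefore unknown, no difference between the lists has a replicate check, and the intervals given below cover counting error only. They treat every region as independent, although many lie close together in the same gene, and may be too narrow. Merging regions up to 1000 bp apart left 647 of 1224 control and 898 of 1986 overexpression regions.

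The question named in the title of the series is whether eIF4G2 acts on mRNAs of the fibrotic programme. In the overexpression list, the transcription factors that carry TGF-beta signals (SMAD2, SMAD4), their inhibitor SMAD7, the repressor TGIF1, the contractility kinase ROCK1 and N-cadherin (CDH2) had bound regions. None of these 6 genes had a region in the control list. The BMP effector SMAD1, the collagen prolyl hydroxylase subunit P4HA1 and the proliferation genes CCNA2 and MKI67 had regions in both lists. The cytoskeletal scaffold gene PALLD, whose regions all lie over CBR4 too, the cap-binding protein gene EIF4E and the COPII coat genes SEC24D and SEC31A had regions in the control list and none in the overexpression list. The split followed the chromosomes: the first 6 genes all lie on chromosome 18, where the control list had no region at all, and the last 4 lie on chromosome 4, where the control list was the longer.

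EIF4G2 itself, the overexpressed gene, had no region in either list. It lies on chromosome 11, where neither list had a region, so the overexpression could not be checked from the lists.

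The overexpression list held 1986 regions covering 1.29 Mb and the control list 1224 regions covering 1.06 Mb. Chromosome 18 carried 1339 regions of the overexpression list, 67.4% of it, and none of the control list. Chromosome 4 went the other way, with 491 regions in the overexpression list and 1185 in the control list. Chromosome 10 had 121 and 29 regions, and all other chromosomes together 35 and 10. Of the RefSeq protein-coding genes, 161 of 270 on chromosome 18 (59.6%) had a region in the overexpression list. On chromosome 4, 210 of 770 (27.3%) had a region in the overexpression list and 332 of 770 (43.1%) in the control list, and on chromosome 10, 67 and 30 of 734 (9.13% and 4.09%). No region of either list lay on 15 of the autosomes, which hold 14872 protein-coding genes.

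**Figure D1:**
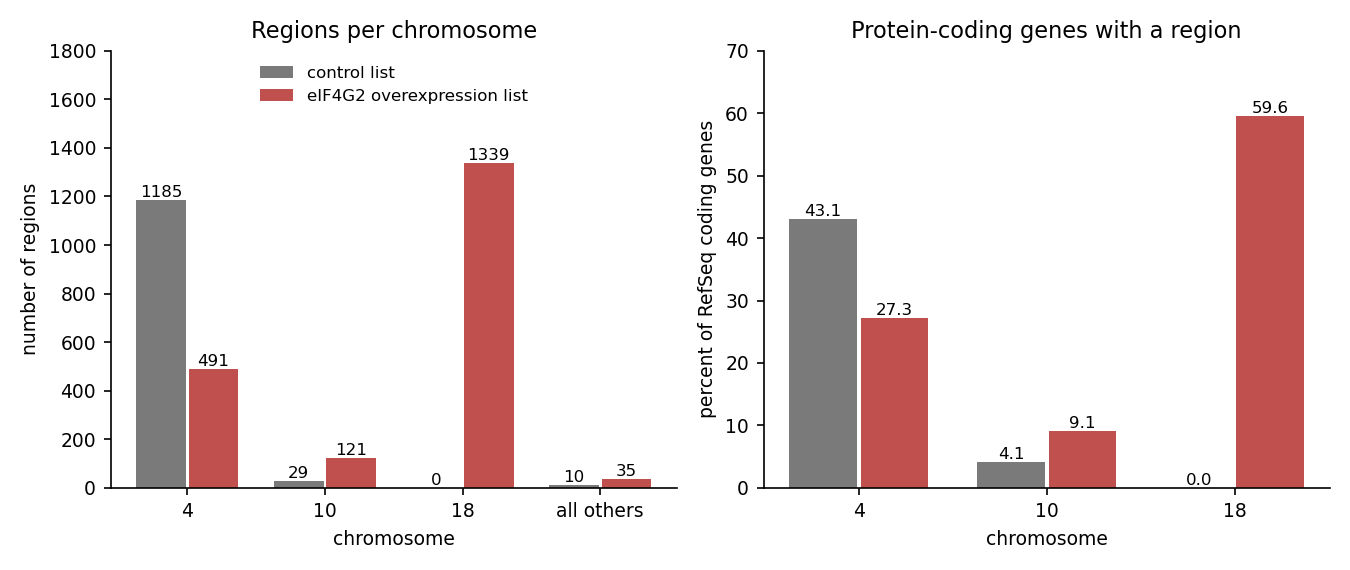
Left, the number of bound regions (vertical axis) on chromosomes 4, 10 and 18 and on all other chromosomes in the control list (grey) and the overexpression list (red). Right, the percent of RefSeq protein-coding genes on chromosomes 4, 10 and 18 with at least 1 region; chromosome 18 had 1339 regions in the overexpression list and 0 in the control list, while chromosome 4 had 491 and 1185.

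Among the genes with regions in the overexpression list only, those with the widest regions were RPL17, a protein of the large ribosomal subunit, and the RPL17-C18orf32 readthrough gene, which share a region on chromosome 18 at 49488271 to 49494790 (6520 bp) in the authors' deposited table. It was followed by CCBE1, a secreted factor of lymphatic growth, with 18 regions that summed to 9220 bp, and by CTIF, a translation factor that works with the nuclear cap-binding complex, with 11 regions (7425 bp). FBXL15, a ubiquitin ligase subunit, and PSD shared a region on chromosome 10 at 102421076 to 102425380 in the authors' deposited table, which also lies over CUEDC2, and without strand it cannot be given to 1 of these genes. LARP4B, an RNA-binding protein, had 1 region of 4100 bp, and CXXC1, a reader of unmethylated CpG, had 2 regions (4155 bp). The ubiquitin ligase NEDD4L had 15 regions (8825 bp), and the antisense transcript WAC-AS1 had 1 (3690 bp). ROCK1 had 40 regions summing to 23185 bp, and ATP8B1, also on chromosome 18 and named after its values were seen, had 38 (21720 bp).

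Among the genes with regions in the control list only, the 10 with the widest regions all lay on chromosome 4. PDLIM5, a PDZ and LIM domain protein of the cytoskeleton, had 3 regions (5430 bp), the widest at 94664201 to 94668800 in the authors' deposited table. GRPEL1, a co-chaperone of mitochondrial import, had 3 regions (4600 bp), and the actin-binding protein gene AFAP1 had 5 (5985 bp), 3 of them also over its antisense transcript AFAP1-AS1. The splicing genes PLRG1 and HNRNPDL had 2 regions (3625 bp) and 4 regions (6510 bp). ANTXR2, an anthrax toxin receptor that binds matrix proteins, had 1 region of 2915 bp and MRFAP1 1 of 2895 bp. The lysosomal membrane protein gene TMEM192 had 3 regions (5425 bp), and SEC24D, which selects cargo for transport out of the endoplasmic reticulum, had 7 (5155 bp).

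The ranking on chromosome 4 alone was added after the data were seen, since chromosome 18 could not give a comparison. On chromosome 4, 43 genes had regions in the overexpression list and none in the control list. Those with the widest regions were the lysosomal enzyme gene IDUA (2 regions, 2625 bp), the pseudogene FAM86EP (2 regions, 2745 bp), the autophagy regulator TBC1D14 (1820 bp) and the transcription factor gene KLF3 (1800 bp). TIGD2 (1350 bp), FAM53A (1340 bp) and ARHGEF38 (1295 bp) came next, then C1QTNF7-AS1 and CPEB2, a cytoplasmic polyadenylation element binding protein, which shared a region of 1290 bp. The lymphangiogenic growth factor gene VEGFC had 2 regions (1720 bp). The region of ARHGEF38 also lies over INTS12, a gene with regions in both lists, and those of FAM86EP, TBC1D14 and VEGFC also lie over unnamed genes, so without strand they cannot be given to 1 gene.

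Between the lists, 244 genes were shared, out of 471 in the control list and 634 in the overexpression list. Of the 390 genes found in the overexpression list only, 63.8% lay on chromosome 18, 17.7% on chromosome 10 and 11.0% on chromosome 4. Over all chromosomes 38.5% of the genes of the overexpression list were also in the control list, and on chromosome 4 the share was 84.0% (225 of 268). In the other direction the shares were 51.8% over all chromosomes and 52.3% on chromosome 4 (225 of 430). On chromosome 10, 16 genes were shared out of 85 and 34; they included CXCL12, a chemokine of stromal cells, the mitotic genes CEP55 and BUB3, and the nucleolar protein gene NOLC1, which were chosen after their values were seen. Among protein-coding genes of chromosome 4, 185 were in both lists, against 90.5 for independent lists of this length (332 × 210 / 770). Random sets of 210 genes matched on gene length held a median of 98 genes of the control list. Of 10000 sets, 0 held as many as 185. Neither comparison took expression into account, and both used all 770 genes, of which 357 had a region in either list. Expression of the same genes in both conditions therefore cannot be told apart from shared binding by eIF4G2.

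The regions themselves overlapped as follows. Of the overexpression regions 333 of 1986 (16.8%, 95% Wilson interval 15.2 to 18.5) shared at least 1 bp with a control region, and of the control regions 315 of 1224 (25.7%, 23.4 to 28.3). On chromosome 4 the shares were 319 of 491 (65.0%, 60.6 to 69.1) and 302 of 1185 (25.5%, 23.1 to 28.0), and on chromosome 10 12 of 121 (9.92%, 5.76 to 16.5) and 12 of 29 (41.4%, 25.5 to 59.3). When the 473 overexpression regions in genes of chromosome 4 were placed at random within the span of their own genes, 76.2 overlapped a control region on average over 1000 placements, with a maximum of 96, while 311 did so where they were listed. Even placement leaves out that regions of both lists were frequent in the last 10% of transcript spans. With each region moved to the relative position of another region, a setting added after the data were seen, 97.0 of 389 regions in genes of 1 strand overlapped a control region on average (maximum 121), against 251 as listed. Exons were not modelled in either placement. On chromosome 13 the control list had 1 region, over TPT1, the translationally controlled tumour protein gene, and its antisense transcript TPT1-AS1, and the overexpression list had 2, which both overlapped that control region.

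Of the 10 genes with the widest regions in both lists, CCNA2, cyclin A2, had regions summing to 8400 bp in the control list and 3675 bp in the overexpression list. The fibroblast growth factor gene FGF5 had 11175 and 7030 bp, and the purine synthesis enzyme gene PAICS 7730 and 3260 bp. ANKRD17, an ankyrin repeat protein, had 18 and 8 regions, and its widest region, at 73074631 to 73076800 on chromosome 4 in the authors' deposited table, had identical ends in both lists. The adaptor SH3D19 had 9230 and 3200 bp, and the transcription factor ELF2 8770 and 5095 bp. In the authors' deposited table, the widest control region of SH3D19 (4945 bp) also lies over RPS3A and SNORD73A. The widest overexpression region of ELF2 (2400 bp) also lies over NOCT. RGS12, a regulator of G protein signalling, was close to even in summed length, with 4595 and 4625 bp, but its widest regions in the control and overexpression lists do not overlap. CALHM2 had 1 region in each list, 2050 and 3280 bp wide in the authors' deposited table, which also lies over PDCD11. TPT1 had 1 region in each list, 3485 and 4305 bp wide.

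Covered length per shared gene was compared in place of a read count, which the lists lack. Regions entered with their full width, so the sum can exceed the gene, as for CCNA2 in the control list (8400 bp). Genes under the same region each received its whole width, so the genes are not separate values. Over the 244 shared genes the median was 2645 bp in the control list and 1552.5 bp in the overexpression list, and the median ratio of overexpression to control was 0.650. Scaled to the total covered length of each list (1288.2 and 1057 kb, with mean region widths of 649 and 864 bp), the median ratio was 0.533. On chromosome 4 alone (425 and 1016 kb, mean widths 866 and 857 bp), 167 of the 225 shared genes had more covered length in the control list and 57 in the overexpression list, with a median ratio of 0.598. Scaling divides the ratio of every gene by the same constant, 0.418 for the totals of chromosome 4, and so gave 1.43; this follows from the lengths of the lists and shows no direction for the shared genes. On chromosome 10, 15 of 16 shared genes were longer in the overexpression list, with a median ratio of 1.60 before scaling and 0.364 after it.

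**Figure D2:**
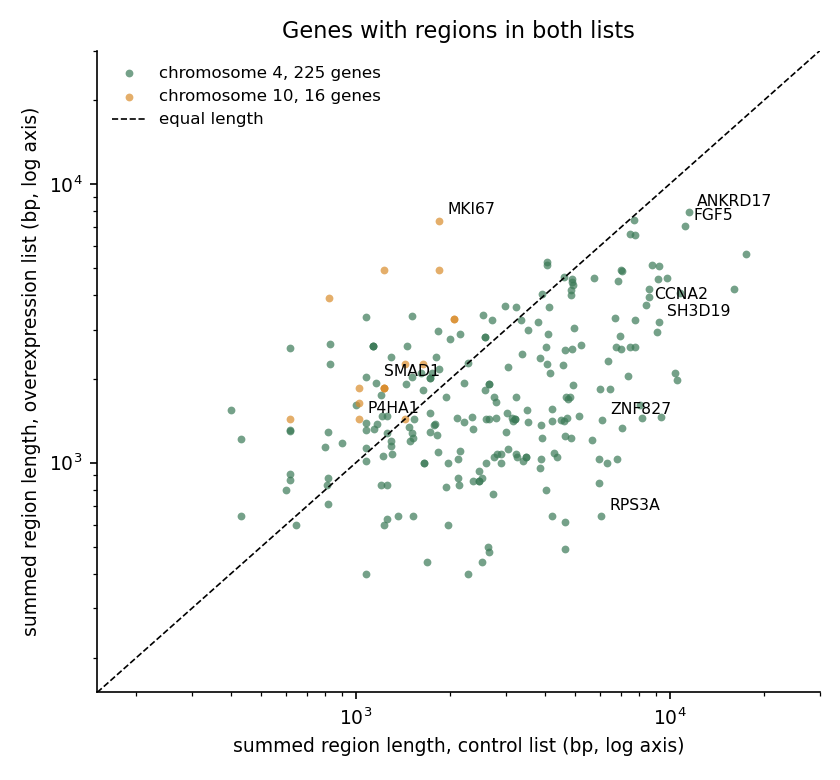
Summed length of the bound regions of each shared gene in the control list (horizontal, bp, log axis) and in the overexpression list (vertical, bp, log axis), with 1 point per gene and a dashed line at equal length. Of the 225 genes on chromosome 4 (green) 167 lie below the line, and of the 16 genes on chromosome 10 (orange) 15 lie above it, before any scaling.

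Of the 33 genes fixed for TGF-beta and BMP signalling, 6 lie on chromosomes 4, 10 and 18, and 5 of these had a region. SMAD2 had 16 regions (8460 bp), the widest at 47832986 to 47834490 on chromosome 18 in the authors' deposited table. TGIF1 had 12 regions (5745 bp), SMAD4 3 (2120 bp) and SMAD7 3 (1660 bp), all in the overexpression list only. SMAD1 had 1 region in each list at the 3′ end of the gene, at 145558441 to 145559600 in the control list and 145557581 to 145559515 in the overexpression list in the authors' deposited table. BMPR1A had none and lies on chromosome 10, where few coding genes had a region (9.13% in the overexpression list and 4.09% in the control list). Of 10000 random gene sets matched on summed region width, 8.70% had 4 or more genes in the overexpression list only, as this list did. With sets matched on chromosome, chosen after the data were seen, every set had as many (100%), since no gene of chromosome 18 was in the control list.

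**Figure D3:**
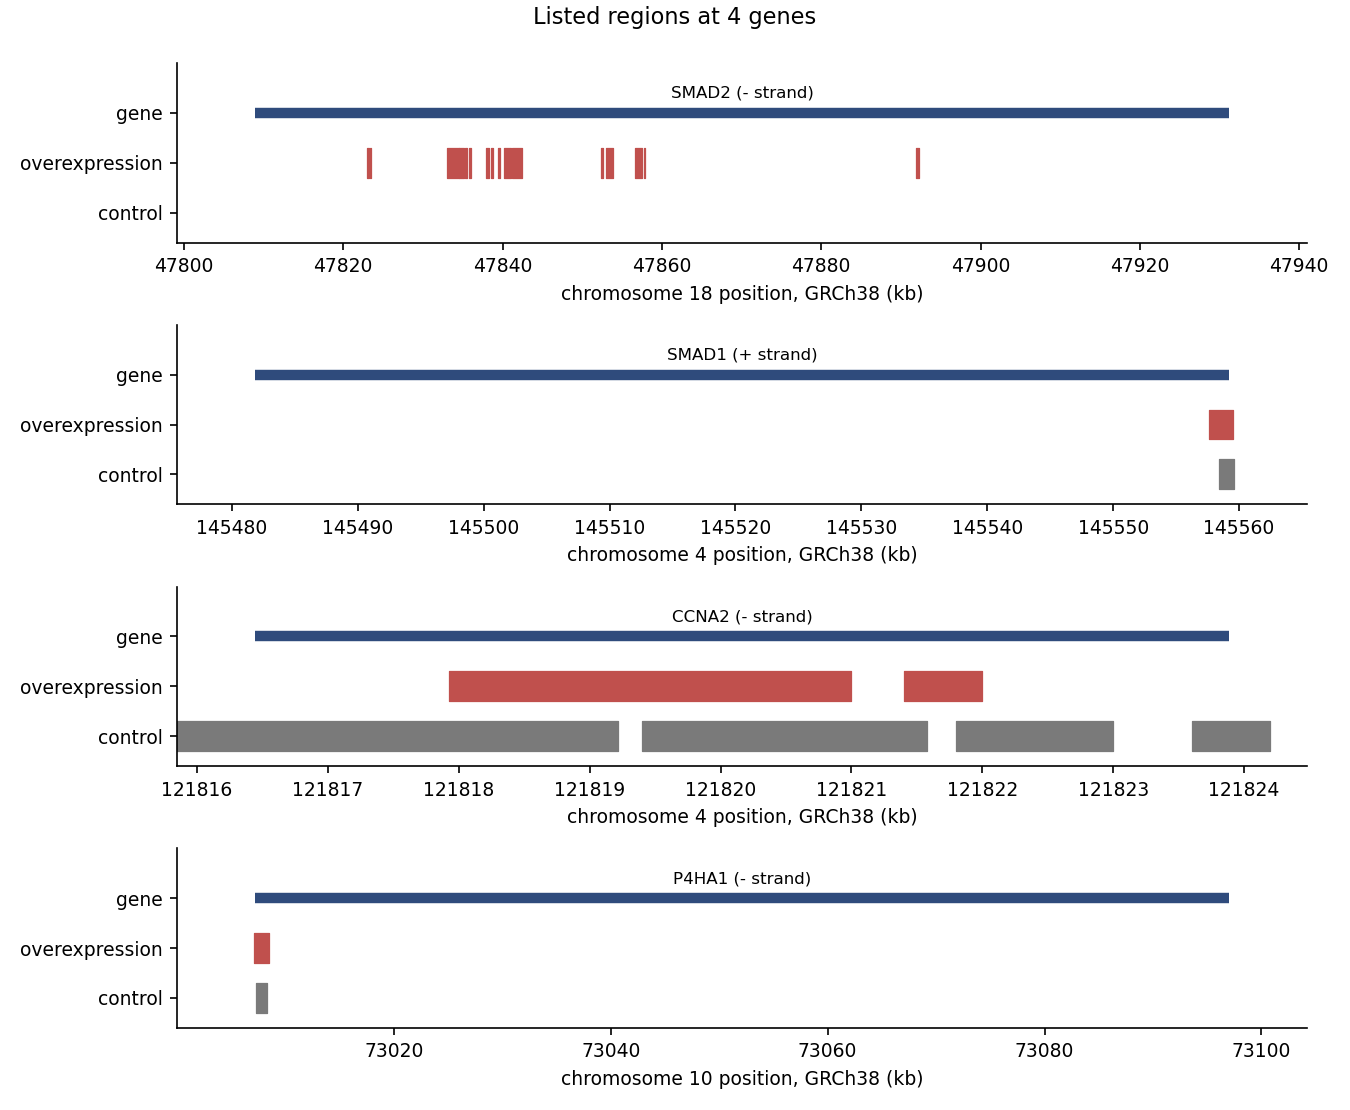
Bound regions of the overexpression list (red) and the control list (grey) at SMAD2, SMAD1, CCNA2 and P4HA1, with the span of the annotated transcripts in blue; the horizontal axes give GRCh38 positions in kb on chromosomes 18, 4, 4 and 10. SMAD2 has 16 regions in the overexpression list and none in the control list, and SMAD1 and P4HA1 each have 1 region per list, at their 3′ ends.

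The 33 genes fixed as structural for the extracellular matrix (collagens, fibronectin and the like) had no region, and none of them lies on chromosomes 4, 10 or 18. Other matrix genes, chosen after their values were seen, did have regions. LAMA1 (1240 bp), LAMA3 (605 bp) and EMILIN2 (4200 bp) on chromosome 18 were in the overexpression list only. FRAS1 on chromosome 4 was in the control list only (1290 bp), with regions that also lie over SERBP1P5. Of the 32 genes for matrix crosslinking and remodelling, 3 lie on chromosomes 4, 10 and 18: P4HA1 had 1 region of 1025 bp in the control list and 1 of 1435 bp in the overexpression list in the authors' deposited table, and ADAM12 and LOXL4 had none. Of the 29 contractile and cytoskeletal genes of myofibroblasts, PALLD had 5 regions in the control list (4255 bp), all 5 of which also lie over CBR4, and CDH2 had 9 in the overexpression list (4040 bp), 3 of them also over an unnamed gene. The other 4 members on these chromosomes, ACTA2, VCL, ITGB1 and VIM, lie on chromosome 10 and had none in either list. Few coding genes of chromosome 10 had a region (9.13% in the overexpression list and 4.09% in the control list). The absence of these 4 genes, and of ADAM12 and LOXL4, therefore does not set them apart, and their expression was not examined. Of the growth factor and kinase genes ROCK1 had regions and PDGFRA, on chromosome 4, had none.

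Of the 10 mRNAs reported as cap-independent targets of eIF4G2, BCL2 and CDK1 lie on chromosomes 18 and 10 and had no region, and the others, on other chromosomes, had none either. CDK1, and KIF11 named below, lie on chromosome 10, where few coding genes had a region (9.13% in the overexpression list, 4.09% in the control list). Of the 28 translation initiation factors, EIF4E had 1 region of 2455 bp in the control list in the authors' deposited table, and EIF3A, the largest subunit of eIF3, had 3 in the overexpression list (1435 bp). Of the 24 genes of endoplasmic reticulum stress and secretion, SEC31A (5410 bp) and SEC24D were in the control list only. Of the 28 cell cycle genes, CCNA2 and MKI67 were in both lists, MKI67 with 1 region in the control list (1845 bp) and 6 in the overexpression list (7380 bp), and KIF11 in neither. Fewer than 3 members of each of these lists had a region, so no random sets were drawn for the share in the overexpression list only.

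All 5 of the 77 cytosolic ribosomal protein genes that lie on chromosomes 4, 10 and 18 had a region. RPL9 (4640 bp in the control list, 615 bp in the overexpression list), RPL34 (4200 and 1555 bp) and RPS3A (6020 and 645 bp) were in both lists, and RPL17 and RPS24 (6150 bp) in the overexpression list only. The widest control region over RPS3A also lies over SH3D19, and its only overexpression region also lies over SNORD73B. The only region of RPL17 also lies over RPL17-C18orf32, SNORD58A, SNORD58B, SNORD58C and an unnamed gene. It cannot be given to RPL17 alone, and the 5 of 5 counts it. For members with a region in either list, random sets matched on chromosome and gene length were added after the data were seen, for the 6 lists with at least 3 members on these chromosomes. Of these sets 0.130% had 5 of 5 genes with a region, as the ribosomal protein genes did. The sets were not matched on expression, so abundance of these mRNAs cannot be told apart from preferential binding. As many genes as observed had a region in 16.6% of sets for TGF-beta and BMP signalling (5 of 6), 8.60% for the cell cycle (2 of 3) and 10.3% for zinc finger genes (13 of 28). The values were 27.0% for matrix crosslinking (1 of 3) and 53.4% for the myofibroblast genes (2 of 6). Matched on region width, 55.0% of sets had at least 2 genes in the overexpression list only, as the ribosomal protein genes did.

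Of the 477 zinc finger genes, 28 lie on chromosomes 4, 10 and 18, and 13 of these had a region: 3 in both lists, 2 in the control list only and 8 in the overexpression list only. ZNF721 (4840 and 3980 bp) and ZNF827 (6060 and 1425 bp) were among the shared ones, and ZNF22 (2460 bp) and ZNF532 (2290 bp) among those of the overexpression list only. Of the random sets matched on region width, 13.2% had 8 or more such genes, and 78.7% of those matched on chromosome.

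In the mitochondrial genome the control list had 2 regions, over MT-CYB and MT-ND6, and the overexpression list none. Of the 20 housekeeping genes TPT1 had regions. The 74 replication-dependent histone genes, the 13 nuclear long noncoding RNAs and the marker genes of cardiomyocytes (15), immune cells (12), smooth muscle cells and pericytes (10) and epithelial cells (10) had no region, and none lies on chromosomes 4, 10 or 18. Of the 12 endothelial markers EMCN and KDR lie on chromosome 4, and neither had a region.

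Most regions lay in annotated genes, 94.0% (1867 of 1986, 92.9 to 94.97) in the overexpression list and 91.1% (1115 of 1224, 89.4 to 92.6) in the control list. Regions over more than 1 gene made up 20.6% and 17.5%, and regions over genes of both strands 15.8% and 14.4%; the lists give no strand, so these cannot be assigned to 1 gene. Among the named genes these included 26 of 38 regions of ATP8B1, 8 of 18 of CCBE1, 2 of 3 of SMAD4, 1 of 16 of SMAD2, 1 of 7 of SEC31A, 1 of 4 control regions of CCNA2 (over EXOSC9), 4 of 5 control regions of ZNF721 (over ABCA11P, PIGG or an unnamed gene), the region of ZNF22 (over CEP164P1) and the overexpression region and 1 of 2 control regions of ZNF827 (over C4orf51). Within protein-coding transcripts of at least 5000 bp, 35.6% of overexpression regions (33.1 to 38.3, 469 of 1316) and 37.6% of control regions (34.3 to 41.0, 306 of 814) had their midpoint in the last 10% of the transcript span, introns included. The first 10% held 7.07% and 8.85%. Only regions over 1 gene entered, each within the longest transcript it overlapped. Exons were not known, so these shares alone do not show a preference for the 3′ end of the mRNA. The share in the last 10% was 32.5% (29.5 to 35.7) for chromosome 18 and 40.4% (35.2 to 45.7) for chromosome 4 in the overexpression list, and 36.3% (33.0 to 39.7) for chromosome 4 in the control list. For chromosome 10 it was 45.6% (35.0 to 56.5, 36 of 79) in the overexpression list and 82.6% (62.9 to 93.0, 19 of 23) in the control list. The median region width was 235 bp on chromosome 18, 755 bp on chromosome 4 and 1025 bp on chromosome 10 in the overexpression list, and 600 bp on chromosome 4 and 1230 bp on chromosome 10 in the control list.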

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

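Regions outside annotated genes were not used by the comparisons of genes. The control list had 109 such regions and the overexpression list 119. Of these, 19 and 36 lay within 1000 bp of a gene, with median distances of 3449 and 2971 bp, and 97 of those in the overexpression list lay on chromosome 18.

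On chromosome 21 the control list had 7 regions, covering 2640 bp in all, and the overexpression list had none there. All of them lie between 8216781 and 8670860 in the authors' deposited table. Their nearest named genes there, 5.8S ribosomal RNA genes for 4 regions and the pseudogene RPSAP68 for 2, are 2528 to 45868 bp away. Among the 7 regions, 1 of 220 bp lies inside or over an unnamed gene. No explanation was tested for either result.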

How the results depend on the processing

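Of 72 alternative values, 45 stayed within the bounds set for them and 27 moved; alternatives by chromosome, by 400 bp width, by 1 gene, by bin grid and without scaling were chosen after the data were seen. The bounds were wide, so the 45 are not all stable values. Matching on chromosome took the percentage of random sets from 8.70% to 100% for TGF-beta and BMP signalling. For zinc finger genes it went from 13.2% to 78.7%. Regions over 1 gene only took the control list from 471 to 328 genes. All 3 counted as within bounds. Merging regions up to 1000 bp apart left 647 control and 898 overexpression regions. Requiring 50% of both regions lowered the shared regions to 7.96% of the overexpression list and 12.9% of the control list. On chromosome 4 only, the overexpression list had 491 regions, of which 65.0% were shared, and 268 genes, 43 of them absent from the control list; without chromosome 18, 51.5% of its regions were shared. With regions of at least 400 bp, 1135 overexpression regions stayed, and 28.4% of overexpression and 30.3% of control regions were shared. With boundaries on both bin grids, 316 control and 519 overexpression regions stayed, 14.2% and 8.86% of them shared, over 244 and 340 genes, 82 in both lists and 258 in the overexpression list only. With regions over 1 gene only, the overexpression list had 414 genes, 159 were shared and 255 were in the overexpression list only. The ratio of covered length was 0.650 without scaling and 1.43 on chromosome 4 scaled to its total. Weighting by width put 94.7% of the control and 96.2% of the overexpression list in genes. Fewer regions enter under most of these settings; otherwise the cause was not tested. The percentages of random sets with as many genes in the overexpression list only stayed above 5% for TGF-beta and BMP, ribosomal protein and zinc finger genes under every alternative run for that measure. For TGF-beta and BMP signalling this says little, since even 4 of its 5 listed genes were matched by 8.70% of sets.

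No paired analysis was possible because the lists carry no values per replicate, and leaving out replicates, other normalizations and tests per replicate were not run for the same reason. A stricter p or q, the regions above the median score, lists of equal length by score and ignoring strand were not run, since the tables hold no score, p-value or strand. Scaling by the median ratio of shared genes sets that median to 1 by construction and was not listed. Depth limits every absence, since it is unknown.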

Other observations

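The tests in this part were all chosen after the results were seen. Some gene families on chromosome 4 had no region in either list; they were picked after this was seen, so no share was tested. They were the 10 UDP-glucuronosyltransferase genes of the UGT2 family, the 3 caseins, the 3 class I alcohol dehydrogenase genes, the 4 subunit genes of GABA-A receptors and the 5 Toll-like receptor genes. Of the genes for plasma proteins made in the liver, ALB, AFP, GC, FGA, FGB and FGG had none, and KLKB1, plasma prekallikrein, had a control region of 1255 bp that also lies over CYP4V2, so without strand it cannot be given to either gene. The fibroblast growth factor genes FGF2 and FGF5 had regions in both lists, though all 3 control regions and 2 of 3 overexpression regions of FGF2 also lie over NUDT6. Of the 10 CXC chemokine genes of chromosome 4 with a CXCL symbol, CXCL8 and CXCL3 had regions in the control list only.

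Outside chromosomes 4, 10 and 18 the overexpression list had 22 regions on chromosome X, over genes such as the histone methyltransferase gene SUV39H1, the splicing protein genes RBM10 and PQBP1, the deubiquitinase genes USP9X and USP11 and the pseudouridine synthase gene DKC1. It had 6 regions on chromosome 6 (over genes such as BAG6, TRAM2, KLHDC3 and MEA1) and 4 on chromosome 16 (CLCN7, RNF40 and VPS35). The control list had no region at these genes.

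Regions lay almost only on chromosomes 4, 10 and 18, which hold 8.85% of RefSeq protein-coding genes but 98.2% of overexpression and 99.2% of control regions. A preference of eIF4G2 for single mRNAs whatever their chromosome is argued against by these shares themselves. The ribosomal protein genes, a class fixed before the data were examined, showed the same split. Of them, 100% of the 5 on these chromosomes had a region (95% Wilson interval from 56.6%) and none of the 72 elsewhere. That 0% elsewhere follows from the pattern itself, so the class is no separate test of such a preference. Nor is it a test of calling that differed between chromosomes, which stays open. A loss of numbered regions from among those listed is argued against by the 0 missing region numbers. These cannot show a loss of regions after the highest number or a renumbering after a loss. A loss of whole chromosomes before numbering stays open too, since the numbers cannot show it, and the lists may thus be only part of what was bound.

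Chromosome 18 had 1339 regions in the overexpression list and none in the control list. Greater depth of the overexpression libraries as the whole cause is argued against by chromosome 4, where the overexpression list had 0.414 times the regions of the control list. This holds only if calling was alike across chromosomes. Chromosome 10 (121 overexpression and 29 control regions) and all other chromosomes together (35 and 10) went the other way, so depth as part of the cause stays open. Calling that differed between chromosomes is consistent with the median region width, 235 bp on chromosome 18 against 755 bp on chromosome 4 and 1025 bp on chromosome 10 of the same list. Binding gained by mRNAs of chromosome 18 on overexpression, SMAD2, SMAD4, SMAD7, TGIF1 and ROCK1 among them, cannot be told apart from this, because the control list had 0 coding genes with a region on that chromosome under either account and no values per replicate were used here.

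Region boundaries lay on fixed grids: all regions (100% of boundaries) on chromosome 4 in both lists began just after and ended on multiples of 200 or 215 bp, those on chromosome 10 in both lists of 205 bp, and those on chromosome 18 in the overexpression list of 205 or 215 bp, against 4.77%, 2.44% and 4.71% by chance for boundaries spaced by 5 bp. A single calling with 1 bin size is argued against, since the most common grid took 61.6% of control boundaries on chromosome 4, and so are 2 joined callings with 1 bin size each for all chromosomes, since the overexpression list had 3 bin sizes on these chromosomes; joined callings whose bin sizes vary by chromosome stay open, and chromosome 10 showed a single grid. Regions of chromosome 4 with 1 boundary on each grid were then tested for recurring more often in the other list: among overexpression regions of 600 to under 1200 bp, 64.8% (54.6 to 73.9) of those on both grids and 70.3% (62.5 to 77.2) of those on 1 grid overlapped a control region, a difference of -5.51 percentage points with overlapping intervals. At 1200 bp and wider 35 of 50 and 48 of 59 regions did so. In the control list 32.3% (27.4 to 37.6) of regions on both grids and 23.02% (20.3 to 25.9) of those on 1 grid overlapped an overexpression region over all widths, with median widths of 1007.5 and 430.0 bp, but 24.2% and 24.4% at 600 to under 1200 bp and 53.4% and 51.3% at 1200 bp and wider.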
